A study of Mus musculus with 33 samples.

How the data were processed

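The samples were livers of 33 male adult mice in 11 groups, hybridised singly to Affymetrix MG-U74Av2 arrays. The series text gives the doses, fasting times and group sizes, and raw scans were not used here. The deposited table holds 12488 probe set intensities per array, with negative values kept, as in average differences of perfect match and mismatch probes. Per the file headers the authors multiplied each array but the first by a scale factor, and the intensity values are not on a log scale. The second deposited table holds the same values for all 12488 probe sets, and detection calls (present, marginal or absent) that the authors' software made. The calls stand under experiment numbers and were not assigned to single samples, so they were only counted over the 33 arrays; 2989 to 5714 probe sets were called present on an array. A further 66 columns of per-array values in that table were not used here.

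The choices named as planned were fixed before the data were examined: the groups, comparisons, gene lists, tests, alternatives and the rule for naming genes. The planned scaling was to 1 common trimmed mean (2% off each side) unless the values already were on a common scale. They were taken as already common, since the mean of the values floored at 30, the floor value in the header of the authors' table, was 118 to 124 on every array. The trimmed means themselves ran from 53.2 to 69.9. This was decided from array summaries, after looking at them and before any test result was seen, and scaling to 1 trimmed mean is given as an added alternative. Values were floored at 6.31 (0.1 of the mean trimmed mean of 63.1) and taken to log2. Control probe sets and those called present on fewer than 3 of 33 arrays were left out, which kept 6568. Probe sets were named by the platform annotation; 10855 carry 1 gene symbol, 396 several and 1237 none, and the annotation is old, so single symbols may be out of date. Positions are from the RefSeq annotation of GRCm38.p6.

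One limma fit with 11 group means gave each contrast with its standard error. Its moderated test used 22 residual and 1.89 prior degrees of freedom, with Benjamini-Hochberg adjustment over the 6568 probe sets and a threshold of 0.05. Folds and log2 changes are from this fit, and intensities are means with SD of the deposited values. Log2 changes of genes whose lower group lies near or at the floor depend on the floor and are not exact. For some genes with every array of the lower group at or below 30 a bound stands beside the change. It is the mean log2 of the higher group (floored at 30) against 30, and is called "at least". Where arrays of the higher group also lie under 30 they are raised to 30, so it is then not a strict bound. The interaction was a limma F-test over the 3 contrasts of the drug effect at 3, 6 and 12 h with that at 0 h. The ratio of responses was taken over probe sets whose response averaged over both drugs passed, so that neither drug selects them.

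Of 37 gene lists fixed beforehand (pathways and markers of cells and organs), 31 had at least 4 measured genes and were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (that of highest mean). Camera with an estimated correlation, fry and means over the probe sets of a gene stand beside it. The text names, per comparison, the 6 largest rises and falls among probe sets that passed, with every array of the higher group above the floor; up to 3 passing members of each list; and 18 fixed genes whatever their p, where measured. Some of these fixed genes are not reported here. Where fewer than 6 passed, those with the 6 smallest p-values are named. The list names are short forms; "gluconeogenic" stands for gluconeogenic and insulin-repressed genes, and "oxidation" for fatty acid oxidation and ketogenesis.

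Arrays were put in set 1 or 2 by the share of values at or below 0, with the border at 31%. The array set as a term in the fit is an alternative chosen after seeing the data, as are a floor of 30, both together, scaling to 1 trimmed mean, and the mean effect of rapamycin over 3, 6 and 12 h. Only the rapamycin groups at 3 and 6 h hold arrays of both sets, so the term rests on 6 arrays. The ratio of 3' to 5' signal ran from 0.844 to 1.07 for the Gapdh controls and from 1.15 to 1.65 for Actb. Pearson's r across probe sets between arrays of a group was 0.906 to 0.975. Replicate numbers pair no samples: deviations of same-numbered arrays from their group means correlated between -0.273 and 0.213 across probe sets.

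The alternatives fixed beforehand were quantile normalization, the floor halved or doubled (3.16 and 12.6), no detection filter or present on 11 arrays, trended robust eBayes, a replicate block, only the 2 groups compared, and leaving out each array. Part of the procedure was run on simulated data, with and without a shift between the array sets. Changes of 1 and 2 log2 units were planted in some probe sets of the rapamycin group at 12 h. The calls at 12 h and 0 h and the response ratio at 6 h were scored. All rapamycin and vehicle arrays at 12 h belong to set 2, so that shift fell on both sides alike. The list tests, the interaction, the mean effect and the splits were not tried this way, and the outcome is not reported here. All calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3; figures were drawn with matplotlib 3.10.9.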

Results

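Liver RNA of 33 male adult mice was measured on 33 oligonucleotide arrays of 12488 probe sets, 1 array per mouse, with no pooling stated. The design asks how rapamycin, an inhibitor of the mTORC1 kinase complex, changes liver transcripts in fasting, in refeeding and without a fast. Mice fasted for 24 h without an injection made up 1 group (n = 5). Other mice were fasted for 22 h, injected with rapamycin at 10 mg/kg or with vehicle, and 2 h later were either killed (0 h) or given food for 3, 6 or 12 h (n = 3 in each of 8 groups). Nonfasted mice were injected with either and killed 24 h later (n = 2 in each group). After control probe sets and those rarely called present were left out, 6568 probe sets were tested, of which 5001 different genes carry 1 symbol. The number of arrays per group limits the precision.

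The arrays fell into 2 sets, and 9 of 11 groups lie wholly in 1 of them. In set 1 (16 arrays) 35.05% to 40.8% of the values lay at or below 0, and in set 2 (17 arrays) 24.2% to 28.2% did. All arrays of the fasted uninjected, vehicle 0 h, vehicle 6 h and nonfasted rapamycin groups belong to set 1. All arrays of the rapamycin 0 h, vehicle 3 h, vehicle 12 h, rapamycin 12 h and nonfasted vehicle groups belong to set 2. The rapamycin group at 3 h holds 1 array of set 1 and 2 of set 2, and that at 6 h holds 2 of set 1 and 1 of set 2. Counts with the array set as a term in the model therefore stand beside the pooled ones.

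**Figure D1:**
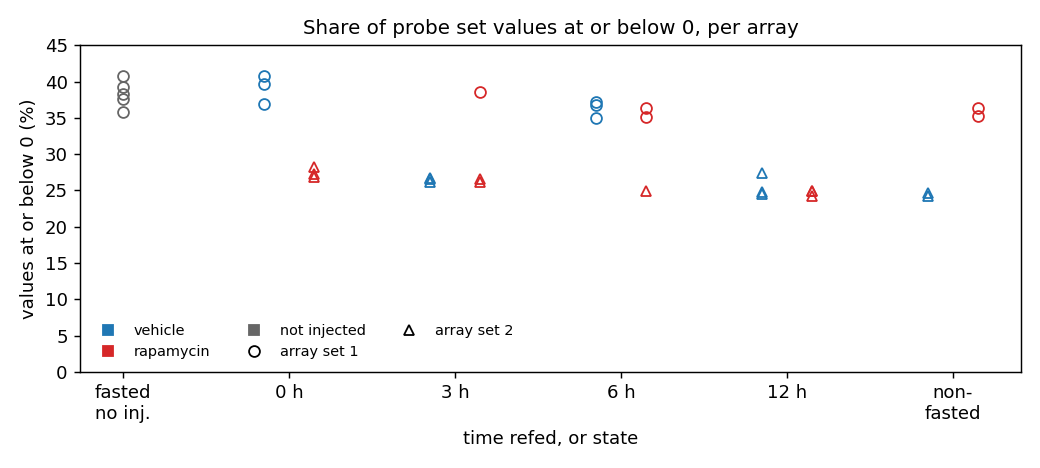
Share of the 12488 probe set values at or below 0 on each array (vertical axis, percent) by time refed or feeding state (horizontal axis); colour gives the injection and the symbol the array set. The arrays of set 1 lie between 35.05% and 40.8% and those of set 2 between 24.2% and 28.2%, and rapamycin and vehicle arrays at 0 h fall in different sets.

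The comparison of vehicle mice refed for 6 h with those at 0 h asks what refeeding changes, and all 6 arrays belong to set 1. Transcripts of cholesterol synthesis rose together: 14 of 16 measured genes were higher and none was lower. Idi1, an isomerase of the isoprenoid part of the pathway, rose from an intensity of 16.7 ± 16.9 to 1256 ± 568 (SD, n = 3 each), a log2 change of 6.50 ± 0.52 (SE). Fdps and Fdft1, enzymes that make and join farnesyl units, rose by 5.98 and 5.64 on the log2 scale, and Msmo1, a sterol oxidase, by 5.54. Igfbp1, a hormone-binding protein repressed by insulin, dropped from 2881 ± 1636.1 to 31.3 ± 31.1, a log2 change of -6.76.

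Gluconeogenic and insulin-repressed genes fell in 8 of 10 measured members, among them G6pc, which releases glucose from the liver, at -2.27, Cebpb at -2.31 and Pck1, a rate-limiting gluconeogenic enzyme, at -1.60. Glucocorticoid targets fell in 8 of 12, including Zbtb16 at -4.38 and Lpin1 at -3.68. Fat synthesis genes rose in 8 of 14 and fell in 1. Fasn, the fatty acid synthase, rose by 4.35, Mid1ip1 by 3.85 and Elovl6, a fatty acid elongase, by 3.83. Srebf1, the transcription factor of this pathway, stood at 1.84 (adjusted p = 0.0503; 0.0431 with the array set as a term and 0.00431 with a floor of 30) and Scd1 at 0.43 (adjusted p = 0.629). Chaperones of the endoplasmic reticulum rose in 13 of 22, among them Pdia6 at 2.22, Pdia4 at 1.44 and Creld2 at 1.41. Genes of autophagy fell in 9 of 26 and rose in 2, with Ulk1, the kinase that starts autophagy, at -1.96 and Map1lc3b at -1.64. Fatty acid oxidation genes fell in 8 of 25 and rose in 1, with Pdk4, which holds back glucose oxidation, at -3.10, Angptl4 at -1.60 and Cpt1a, the gate of mitochondrial fatty acid uptake, at -0.82. Proteasome genes rose in 11 of 37 (Psme3 at 1.27), clock genes rose in 6 of 15 and fell in 3 (Bhlhe40 at 3.95, Dbp at 3.44), and acute phase genes fell in 7 of 23 (Mt1 at -3.78 and Mt2 at -3.34 among them). Igfals, a carrier of circulating growth factor, rose by 5.48 and Lect2, a secreted hepatokine, by 5.49. Every 0 h array lay at the floor for both, so their intensities were at least 9.41-fold and at least 9.45-fold above 30. Cdkn1a, a cell cycle inhibitor, lay at the floor on every 6 h array (log2 change -5.17, at least 7.58-fold lower). Sdc4 at 5.63, and Gpcpd1 at -4.38 and Lepr, the leptin receptor, at -3.98, complete the genes with the largest changes. Sdc4 had -12.3 ± 35.3 in vehicle mice at 0 h but 671 ± 159 in uninjected fasted mice, so its rise depends on which fasted group is compared. Idi1 had 16.7 ± 16.9 and 47.7 ± 18.4 in these 2 groups, and Lpin1 927 ± 177 and 440 ± 171. The sizes of their changes, here and in the later comparisons with vehicle mice at 0 h, therefore depend on it too. Of the genes followed at every time, Ppargc1a stood at -1.81 (-0.22 and adjusted p = 0.123 with the array set as a term and a floor of 30), Eif4ebp1 at -0.94 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.12 (adjusted p = 0.306).

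In all, 931 probe sets rose and 453 fell at 6 h (adjusted p under the threshold of 0.05), and 964 and 512 with the array set as a term. The direction of the split depends on the scaling: 805 rose and 566 fell after quantile normalization, and 732 and 762 after scaling to 1 trimmed mean. The list tests passed for cholesterol synthesis (camera adjusted p = 4.91e-18; adjusted p = 0.0193 with an estimated correlation), for glucocorticoid targets (4.83e-09; adjusted p = 0.0133 with an estimated correlation) and for gluconeogenic genes (3.52e-07; adjusted p = 0.0193 with an estimated correlation). They also passed for chaperones (5.69e-05), fatty acid oxidation (4.65e-04), fat synthesis (0.00142) and acute phase genes (0.0174), but not with an estimated correlation (adjusted p = 0.356, adjusted p = 0.554, adjusted p = 0.22 and adjusted p = 0.588 with an estimated correlation). Those of autophagy, proteasome and clock genes did not pass (0.078, 0.0834 and 0.48). Adjusted over the list alone, 14 cholesterol, 15 chaperone, 9 fat synthesis and 11 proteasome genes were higher, and 8 glucocorticoid, 8 gluconeogenic, 9 autophagy and 9 oxidation genes were lower. The time of day moves with the refeeding time and cannot be separated from it.

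**Figure D2:**
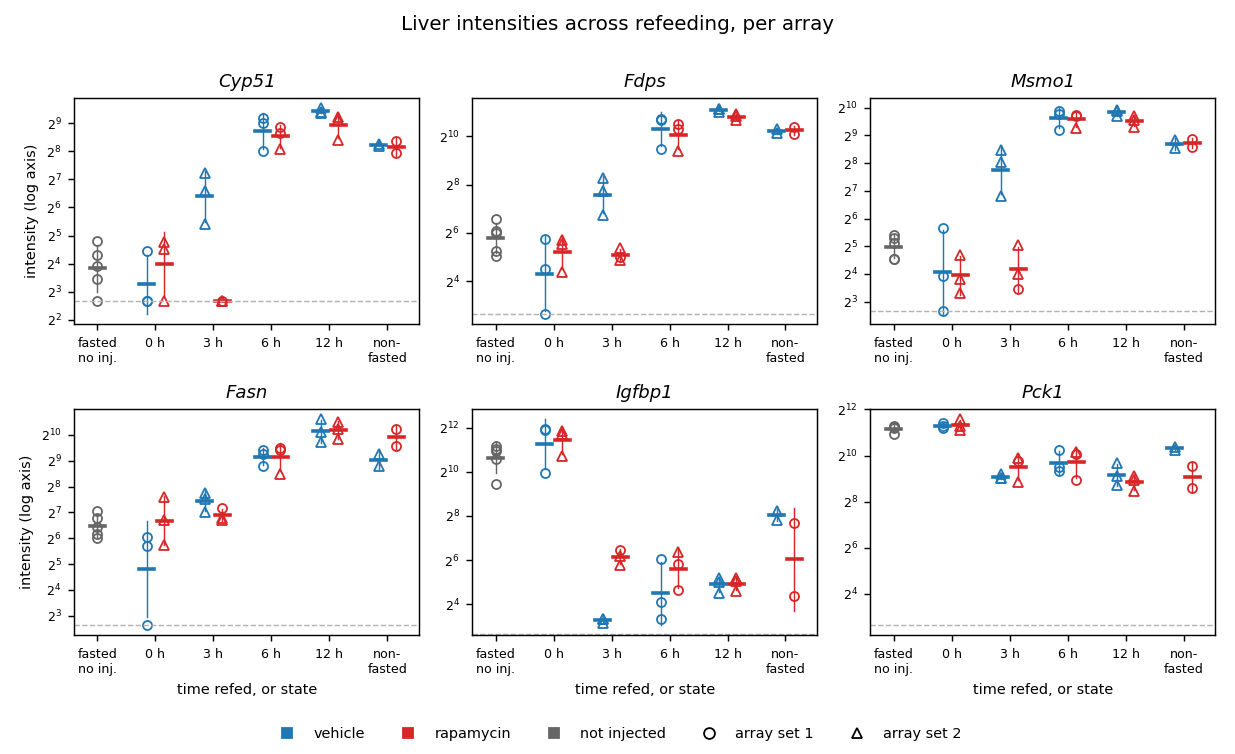
Intensity per array (vertical axis, log scale in base 2, values under the floor of 6.31 drawn at the dashed line) by time refed or feeding state (horizontal axis) for 6 genes; bars are means of the log2 values and thin lines their SD, colour gives the injection and the symbol the array set. Cyp51 lies at the floor on all 3 rapamycin arrays at 3 h and averages 95 in vehicle mice at that time, while Igfbp1 averages 72.0 with rapamycin and 9.67 with vehicle.

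The same comparison at 3 h asks what refeeding changes early. Igfbp1 fell from 2881 ± 1636.1 to 9.67 ± 0.577 (n = 3 each, log2 change -7.98 ± 0.69, at least 81.3-fold lower). Cholesterol synthesis genes were higher in 11 of 16, with Idi1 at 4.23, Fdft1 at 3.81 and Msmo1 at 3.69. Zbtb16 fell by 5.05 on the log2 scale (at least 8.12-fold lower) and Lpin1 by 3.85, and 8 of 12 glucocorticoid targets and 8 of 10 gluconeogenic genes were lower, including Pck1 at -2.22, Cebpb at -2.18 and G6pc at -2.15. Fat synthesis genes were higher in 4 of 14, with Mid1ip1 at 3.28, Elovl6 at 2.73 and Fasn at 2.63, while Srebf1 stood at 0.79 (adjusted p = 0.421) and Scd1 at 0.13 (adjusted p = 0.9).

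Lect2 and Igfals, at the floor on every 0 h array, were at least 4.88-fold and at least 4.47-fold above 30 at 3 h, and Bhlhe40, a clock-linked repressor, was at least 3.40-fold above it. Car3, a carbonic anhydrase, rose by 4.37 and Slc22a30 by 3.96. For Car3 vehicle mice at 0 h had 60.3 ± 65.7 and uninjected fasted mice 254 ± 108, so the size of its rise depends on the fasted group. Ccng2 fell by 3.48 (at least 4.54-fold lower), Cdkn1a by 3.05 and Slc25a47, a mitochondrial carrier, by 2.91. Of fatty acid oxidation genes 3 of 25 were lower (Angptl4 at -1.74, Pdk4 at -1.90, Cpt1a at -0.55), and chaperones of the endoplasmic reticulum were higher in 14 of 22, cytosolic heat shock genes in 8 of 15. Cyp7a1 rose by 2.31, and Ppargc1a fell from 26.7 ± 18.8, itself under 30, to the floor on every 3 h array.

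At 3 h 1304 probe sets were higher and 167 lower, against 118 and 58 with the array set as a term (165 called in both), since all 0 h arrays belong to set 1 and all 3 h arrays to set 2. The median log2 change over all probe sets was 0.27 as deposited and 0.10 with the term, and the split was 542 to 366 after quantile normalization and 736 to 583 after scaling to 1 trimmed mean. With the term Igfbp1, Zbtb16, Lpin1, Idi1 and Fasn still passed (adjusted p = 5.51e-05, 3.77e-04, 3.77e-04, 3.76e-04 and 0.0318), 10 cholesterol genes were higher, and no chaperone passed. Cyp7a1, Cpt1a and Pdk4 did not pass either, at 2.00, -0.29 and -1.80 (adjusted p = 0.38, 0.635 and 0.339). Bhlhe40 did not with the term and a floor of 30 (adjusted p = 0.0973). The list tests passed for cholesterol synthesis (camera adjusted p = 2.07e-07; adjusted p = 0.253 with an estimated correlation), glucocorticoid targets (6.93e-16; adjusted p = 3.98e-04 with an estimated correlation), gluconeogenic genes (3.23e-12; adjusted p = 0.00167 with an estimated correlation), chaperones (0.0041; adjusted p = 0.475 with an estimated correlation), heat shock genes (0.0278; adjusted p = 0.573 with an estimated correlation) and oxidation (3.45e-06; adjusted p = 0.264 with an estimated correlation), and not for fat synthesis (0.516). Adjusted over the list alone, 13 cholesterol, 4 fat synthesis, 15 chaperone and 10 heat shock genes were higher and 9 glucocorticoid, 8 gluconeogenic and 3 oxidation genes lower. Without vehicle 0 h replicate 2 the number of calls was 926, and without vehicle 3 h replicate 2 it was 918.

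At 12 h, where the question is how far the response goes, nearly the whole cholesterol pathway was higher (15 of 16 genes). Idi1 reached 1757 ± 175 from 16.7 ± 16.9 (n = 3 each, log2 change 7.11 ± 0.52), Fdps rose by 6.78, Cyp51, the sterol demethylase, by 6.18, Fdft1 by 5.97 and Msmo1 by 5.75. Fat synthesis genes were higher in 9 of 14 and lower in 1, with Fasn at 5.33, Elovl6 at 4.78, Mid1ip1 at 4.66 and Srebf1 at 3.00, and Scd1 at -0.15 (adjusted p = 0.845). Fatty acid oxidation genes were now lower in 17 of 25 and higher in 1: Acot1 fell by 2.88, Pdk4 by 2.26, Ehhadh, a peroxisomal enzyme, by 1.87 and Cpt1a by 1.07.

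Gluconeogenic genes were lower in 9 of 10 (G6pc at -2.16, Pck1 at -2.13, Ppargc1a at -1.54) and glucocorticoid targets in 8 of 12. Igfbp1 stood at -6.35, Cdkn1a at -4.75, Atg2a, an autophagy gene, at -4.01, Gpcpd1 at -3.91, Lpin1 at -3.63 and Lepr at -3.62. Chaperones of the endoplasmic reticulum were higher in 16 of 22, with Pdia6 at 2.72 and Sec61b, part of the protein channel of that membrane, at 1.74. Of drug metabolism genes 13 of 21 were higher and 5 lower, with Cyp1a2 at 4.53, and of clock genes 5 of 15 were higher and 3 lower, with Nr1d2 at 3.48 and Per2 at 3.38 (at least 2.19-fold above 30). Cyp8b1, a bile acid enzyme, fell by 1.90, and Lect2 was at least 15.7-fold above 30. Urea cycle and amino acid breakdown genes were lower in 11 of 24 and higher in 2.

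At 12 h 1705 probe sets were higher and 611 lower, against 632 and 391 with the array set as a term (905 called in both). The median over all probe sets was 0.24, and the split was 1206 to 1019 after quantile normalization and 1111 to 1253 after scaling to 1 trimmed mean. With the term 14 cholesterol, 8 fat synthesis and 6 chaperone genes were higher and 7 oxidation genes lower, and Srebf1, Ppargc1a and Pdk4 did not pass, at 1.98, -1.54 and -2.16 (adjusted p = 0.171, 0.0651 and 0.109). Lepr did not with the term and a floor of 30 (adjusted p = 0.132). The list tests passed for cholesterol synthesis (camera adjusted p = 1.56e-13; adjusted p = 0.0588 with an estimated correlation), oxidation (2.14e-10; adjusted p = 0.165 with an estimated correlation), gluconeogenic genes (1.74e-08; adjusted p = 0.0264 with an estimated correlation), glucocorticoid targets (5.65e-07; adjusted p = 0.0285 with an estimated correlation), urea cycle genes (3.10e-05; adjusted p = 0.202 with an estimated correlation), chaperones (9.83e-04; adjusted p = 0.392 with an estimated correlation) and fat synthesis (0.00513; adjusted p = 0.202 with an estimated correlation), and not for drug metabolism or clock genes (0.168 and 0.431). With the term and an estimated correlation no list passed at 12 h, with adjusted p = 0.0584 for gluconeogenic genes and 0.0823 for glucocorticoid targets. Adjusted over the list alone, 15 cholesterol, 9 fat synthesis, 16 chaperone and 14 drug metabolism genes were higher, and 18 oxidation, 9 gluconeogenic, 8 glucocorticoid and 12 urea cycle genes lower.

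The comparison of nonfasted with fasted vehicle mice (n = 2 and n = 3) asks what a 24 h fast changes. In nonfasted liver 13 of 16 cholesterol genes were higher (Fdps at 5.91, Idi1 at 5.55, Fdft1 at 5.09) and 10 of 14 fat synthesis genes were higher and 1 lower (Fasn at 4.21, Srebf1 at 3.03, Scd1 at 1.94). Fatty acid oxidation genes were lower in 19 of 25 and higher in 1: Cyp4a10, a fatty acid hydroxylase, had 532 ± 172 against 2915 ± 160 (log2 change -2.49 ± 0.19), Ehhadh stood at -3.27, Acot1 at -3.11 and Cpt1a at -1.37. Igfbp1 was lower at -3.23 and Pck1 at -0.98, and G6pc stood at -0.56 (adjusted p = 0.31).

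Lect2 and Igfals were at least 15.6-fold and at least 14.9-fold above 30 in nonfasted mice and at the floor on every fasted array, and Car3 rose by 5.61. Lower were Cdkn1a at -4.91, Lepr at -4.08, Gpcpd1 at -3.88, Lpin1 at -3.66, Etv4 at -3.59 and Psapl1 at -3.46. Markers of Kupffer cells, the macrophages of the liver, were higher in 7 of 11, among them Csf1r at 1.61 and Lyz2 at 1.37, and growth hormone axis genes in 4 of 12 (Ghr, its receptor, at 1.30). For Csf1r the fasted vehicle mice had 61.3 ± 44.3 and uninjected fasted mice 152 ± 60.1, so its change depends on which fasted group is compared. For Car3 these groups had 60.3 ± 65.7 and 254 ± 108, so the size of its rise does too. Proteasome genes went both ways, with 5 of 37 higher and 11 lower; the immunoproteasome genes Psmb9 and Psmb8 were higher at 3.34 and 2.13. Cycs, cytochrome c, was lower at -1.94 among 9 lower of 61 oxidative phosphorylation genes, and the probe set of Ms4a1, a B cell marker, was lower at -1.61.

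In this comparison 1257 probe sets were higher and 664 lower, against 536 and 498 with the array set as a term (863 called in both), since all fasted arrays belong to set 1 and all nonfasted ones to set 2. The split was 1149 to 922 after quantile normalization and 993 to 1172 after scaling to 1 trimmed mean, and the median over all probe sets was 0.11. With the term Srebf1, Scd1, Pck1, Csf1r, Lyz2 and Etv4 did not pass, at 2.00, 1.23, -1.10, 1.65, 1.20 and -1.09 (adjusted p = 0.185, 0.284, 0.133, 0.0568, 0.156 and 0.583). Lepr did not with the term and a floor of 30 (adjusted p = 0.156). With the term alone 2 Kupffer markers were higher, and 14 oxidation genes were lower. The list tests passed for cholesterol synthesis (camera adjusted p = 1.86e-11; adjusted p = 0.113 with an estimated correlation), oxidation (5.93e-14; adjusted p = 0.113 with an estimated correlation), fat synthesis (0.00719; adjusted p = 0.317 with an estimated correlation), Kupffer markers (0.0411; adjusted p = 0.503 with an estimated correlation), the proteasome (downward, 0.00719; adjusted p = 0.416 with an estimated correlation) and oxidative phosphorylation (0.00719; adjusted p = 0.541 with an estimated correlation), and not for growth hormone genes (0.0529). Adjusted over the list alone, 13 cholesterol, 10 fat synthesis and 8 Kupffer genes were higher and 20 oxidation genes lower. The injection was 24 h old in nonfasted and 2 h old in fasted mice, and without nonfasted vehicle replicate 1 or 2 there were 1117 or 1147 calls, with the lone array assumed to vary like the other groups.

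The comparison of fasted mice injected with vehicle 2 h earlier (n = 3) with uninjected fasted mice (n = 5) asks what the injection changed, and all 8 arrays belong to set 1. Genes of oxidative phosphorylation were higher in 21 of 61 and lower in none, by small amounts: Ndufa8 at 0.89, Uqcr11 at 0.85 and Atp5o at 0.68. Nnmt, a methyltransferase of nicotinamide, was higher at 465 ± 149 against 89.8 ± 66.5 (log2 change 2.78 ± 0.76). Lpin1 and Ppargc1a, both raised in fasting, were higher by 1.17 and 1.37, though Ppargc1a averaged only 26.7 ± 18.8 after injection, under 30. Cholesterol synthesis genes were lower in 3 of 16 (Idi1 at -1.82, Sqle at -1.71 or at least 1.64-fold, Hmgcs1 at -1.37). Sdc4, a cell surface proteoglycan, had -12.3 ± 35.3 after injection against 671 ± 159 without (log2 change -6.48, with 2 of 3 arrays at the floor and at least 21.9-fold lower against 30).

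Pfdn2 was higher at 2.66 (at least 2.04-fold), Plscr1 at 2.37 (at least 1.25-fold), Mrpl34 at 2.16, Abcd4 at 2.15 (at least 1.65-fold) and Sesn1 at 2.00. Pak4, a kinase, lay at the floor on all 3 injected arrays (at least 2.72-fold lower), as did Bdnf, which averaged only 30.3 ± 9.44 without injection. Car3 was lower at -2.78, Pml at -2.48 (at least 1.76-fold) and Umps at -2.47 (at least 1.30-fold). The chaperones Dnajb9 and Hspa5 were higher at 1.07 and 0.66. Stellate cell markers were lower in 2 of 7 (Col3a1 at -1.15, Reln at -0.79), as was the macrophage marker Csf1r at -1.48. Igfbp1 stood at 0.63, Pck1 at 0.13, G6pc at -0.49, Fasn at -1.68 and Scd1 at -1.01, none of them passing (adjusted p = 0.604, 0.889, 0.377, 0.0525 and 0.17). Fasn did pass with a trended robust prior (adjusted p = 0.041) and among probe sets present on at least 11 arrays (adjusted p = 0.0425).

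With the array set as a term and a floor of 30, Idi1, Sqle and Ppargc1a stood at -0.51, -0.71 and 0.22 and did not pass (adjusted p = 0.397, 0.1 and 0.136). Mrpl34, Sesn1, Pml, Umps, Bdnf and Col3a1 did not pass then either (adjusted p from 0.0578 to 1). In all 193 probe sets were higher and 193 lower, and 230 and 117 after quantile normalization, and 279 and 187 after scaling to 1 trimmed mean. The list tests passed for oxidative phosphorylation (camera adjusted p = 2.53e-16; adjusted p = 0.361 with an estimated correlation), cholesterol synthesis (0.0207; adjusted p = 0.467 with an estimated correlation) and stellate markers (0.0096; adjusted p = 0.361 with an estimated correlation), and adjusted over the list alone 34 oxidative phosphorylation genes were higher, and 5 cholesterol and 3 stellate genes lower. The count rests on single vehicle arrays: 92 calls without replicate 1, 59 without replicate 2 and 1141 without replicate 3. There were 244 without uninjected replicate 2.

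Rapamycin against vehicle at 0 h (n = 3 each) asks what the drug changes before food returns. As deposited, 314 probe sets were higher with rapamycin and 38 lower, and none of the genes followed at every time passed: Fasn stood at 1.87 (adjusted p = 0.0564; 0.0439 with a trended robust prior), Cyp7a1 at 1.34, Srebf1 at -1.18, G6pc at 0.19, Igfbp1 at 0.17, Pck1 at 0.02 and Cpt1a at -0.04 (adjusted p from 0.294 to 1 for these 6). The named rises with the largest log2 change had most vehicle arrays at the floor. Pak4 had 81.0 ± 35.4 with rapamycin and lay at the floor on all 3 vehicle arrays (log2 change 3.59 ± 0.38, at least 2.54-fold above 30). Lect2, Ngef and Trp53i13 were at least 3.15-fold, at least 2.16-fold and at least 1.97-fold above 30 with all vehicle arrays at the floor, and the chemokine Cxcl1 and Tgfbr3 were higher at 3.73 and 2.95.

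Lower were Cttn at -2.26, Snd1 at -2.11, Arpc4 at -2.10, Uck1 at -2.09, Sars2 at -2.08 and Plscr1 at -2.02. Cell cycle genes were higher in 3 of 11 (Rrm2 at 1.97, Mki67 at 1.92, Cdc6 at 1.26), and clock genes in 3 of 15 with 1 lower (Bhlhe40 at 2.82, Usp2 at 2.12, Nr1d2 at 2.10). Pik3r1, a subunit of the insulin-signalling lipid kinase, was higher at 2.01, the haemoglobin gene Hba-a1 lower at -1.02 and Cox7b lower at -0.65.

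The 3 vehicle arrays belong to set 1 and the 3 rapamycin arrays to set 2, and with the array set as a term 3 probe sets passed, 2 of them called in both. Of the genes named here Pak4 alone still passed with the term (log2 change 4.12, adjusted p = 6.23e-04; 1.87 and adjusted p = 0.546 with a floor of 30 too), Mki67 turned to -0.34, and no cell cycle gene passed. Uninjected fasted mice had 87.3 ± 40.1 for Pak4, near the 81.0 ± 35.4 with rapamycin, so the vehicle 0 h group is the one that stands apart. With the term and a floor of 30 Cttn, Pik3r1, Bhlhe40 and Nr1d2 changed direction too. The split was 120 to 117 after quantile normalization and 254 to 138 after scaling to 1 trimmed mean, and the median over all probe sets was 0.13. The cell cycle list passed (camera adjusted p = 2.03e-04; adjusted p = 0.0418 with an estimated correlation; adjusted p = 0.155 with the term and an estimated correlation; 8 higher adjusted over the list alone), and the clock list did not (0.31). There were 183, 199 and 866 calls without vehicle replicate 1, 2 or 3, and 164 without rapamycin replicate 2.

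At 3 h of refeeding the question is what the drug changes early in the response. Cholesterol synthesis genes were lower with rapamycin in 8 of 16 and higher in none. Cyp51 (chromosome 5, 4080674 to 4104697 in GRCm38.p6) lay at the floor on all 3 rapamycin arrays against 95 ± 53 with vehicle (n = 3 each, log2 change -3.73 ± 0.55, at least 2.80-fold lower). Msmo1 had 20 ± 11.5 against 243 ± 122 (log2 change -3.60 ± 0.52), and Idi1 stood at -2.73, Mvd at -2.58 (at least 1.72-fold lower), Fdps at -2.51 and Sqle, the squalene oxidase, at -2.06. Outside this pathway Tmem62 was higher at 2.91 (at least 2.06-fold) and Pnliprp2, a lipase on the list of pancreas markers, lower at -1.99 (at least 1.90-fold). Igfbp1 (chromosome 11, 7197787 to 7202546) had 72.0 ± 16.5 against 9.67 ± 0.577, with every vehicle array under 30, so its intensity was at least 2.36-fold above 30. Its log2 difference of 2.87 did not pass (adjusted p = 0.0764) but did after quantile normalization (adjusted p = 0.0126) and with a trended robust prior (adjusted p = 0.0493). With the array set as a term and a floor of 30 it was 1.32 (adjusted p = 0.683).

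Other genes of feeding did not pass: Srebf1 stood at -1.17, Scd1 at -1.08, Fasn at -0.55, Pck1 at 0.42, Cpt1a at 0.27, G6pc at 0.18, Pdk4 at -0.21, Pklr at -0.20, Asns at -0.20 and Cyp7a1 at -0.04 (adjusted p from 0.626 to 1). Chaperones of the endoplasmic reticulum had a median of -0.52 over 22 genes; none passed over all probe sets, and 11 were lower adjusted over the list alone. In all 1 probe set was higher and 19 lower, and 1 and 13 with the array set as a term (13 called in both), where 7 cholesterol genes were lower. The cholesterol list passed (camera adjusted p = 3.72e-23; adjusted p = 0.0178 with an estimated correlation; adjusted p = 0.0114 with the term and an estimated correlation), with 11 lower adjusted over the list alone. The chaperone list passed only with the preset correlation (3.55e-09; adjusted p = 0.202 with an estimated correlation). With the term and a floor of 30 Mvd stood at -0.91 (adjusted p = 0.629). With the term alone Fdps, Tmem62 and Pnliprp2 did not pass, at -2.66, 2.95 and -1.86 (adjusted p = 0.0582, 0.0538 and 0.127). There were 6 and 9 calls without vehicle replicate 2 or 3 and 8, 51 and 9 without rapamycin replicate 1, 2 or 3. Without rapamycin replicate 3 all arrays left belong to set 2.

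At 6 h, the same question gave 1 probe set that passed. Eif4b (chromosome 15, 102073773 to 102097173), a cofactor of the helicase that opens mRNA for translation, was higher with rapamycin at 285 ± 31.5 against 125 ± 16.5 (n = 3 each, log2 change 1.19 ± 0.20, adjusted p = 0.0233; adjusted p = 0.0471 with the array set as a term). The next smallest p-values belonged to Otud5 at 1.48, Lgals4 at 1.73, Slc22a5, a carnitine transporter, at 1.14, Dclre1a at 1.29 and Ulk1 at 1.12, none passing (adjusted p from 0.077 to 0.168). Otud5 did pass with the array set as a term (adjusted p = 0.0471) and scaled to 1 trimmed mean (adjusted p = 0.0406), and Lgals4 and Dclre1a with the floor halved (adjusted p = 0.00926 each). None of these 3 did with the term and a floor of 30 (adjusted p from 0.622 to 1). No gene of feeding passed: Fasn stood at -0.03, Srebf1 at 0.18, Scd1 at -0.14, Pck1 at 0.02, G6pc at -0.43, Cpt1a at 0.40, Asns at 1.67, Igfbp1 at 1.12 and Pklr at 0.82 (adjusted p from 0.742 to 1). The chaperone list had a median of -0.31 with 5 of 22 lower adjusted over the list alone (camera adjusted p = 6.56e-10; adjusted p = 0.198 with an estimated correlation; adjusted p = 0.0394 with the term and an estimated correlation). With the term 4 probe sets passed, and 392 had an unadjusted p under 0.05 as deposited. No probe set passed without vehicle replicate 1 or 2 or without rapamycin replicate 3, the one array of set 2. There were 3 calls without vehicle replicate 3 and 7 without rapamycin replicate 2.

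At 12 h all 6 arrays belong to set 2. Eif4b was again higher with rapamycin at 237 ± 13.5 against 125 ± 30 (n = 3 each, log2 change 0.95 ± 0.20), and so were Cox7a2l, an assembly factor of respiratory complexes, at 0.81, Rmnd5a at 0.75 and Rnf103, a ubiquitin ligase of the endoplasmic reticulum, at 0.71, as well as Mme and Pag1 at 0.96 and 0.80. Fkbp11, a folding enzyme of the secretory pathway, was lower at 16.7 ± 9.29 against 59.3 ± 15.5 (log2 change -1.999 ± 0.36, at least 1.93-fold lower). Lrrc59, a ribosome-binding protein of the endoplasmic reticulum, was lower at -0.83, Gnpnat1 at -0.82, Psmd14, a proteasome subunit, at -0.80 and Ppa1 at -0.61. Foxk2 passed too (log2 change -1.33), with all rapamycin arrays at the floor and vehicle arrays just above it. All arrays of Mme, Pag1 and Foxk2 lay at or under 30, so these 3 show no change above background.

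Fasn stood at 0.05, Srebf1 at 0.17, Pck1 at -0.33, G6pc at 0.25 and Cpt1a at 0.48, none passing (adjusted p from 0.405 to 1). The chaperone list had a median of -0.49, with 10 of 22 lower adjusted over the list alone and none over all probe sets (camera adjusted p = 6.47e-12; adjusted p = 0.151 with an estimated correlation; adjusted p = 0.0489 with the array set as a term and an estimated correlation). In all 8 probe sets were higher and 13 lower, and 9 and 17 with the term. With the floor of 30 these were 16 and 52, and 17 and 60 with that floor and the term, so the count depends on the floor. There were 5, 9 and 13 calls without rapamycin replicate 1, 2 or 3 and 34 without vehicle replicate 3.

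**Figure D3:**
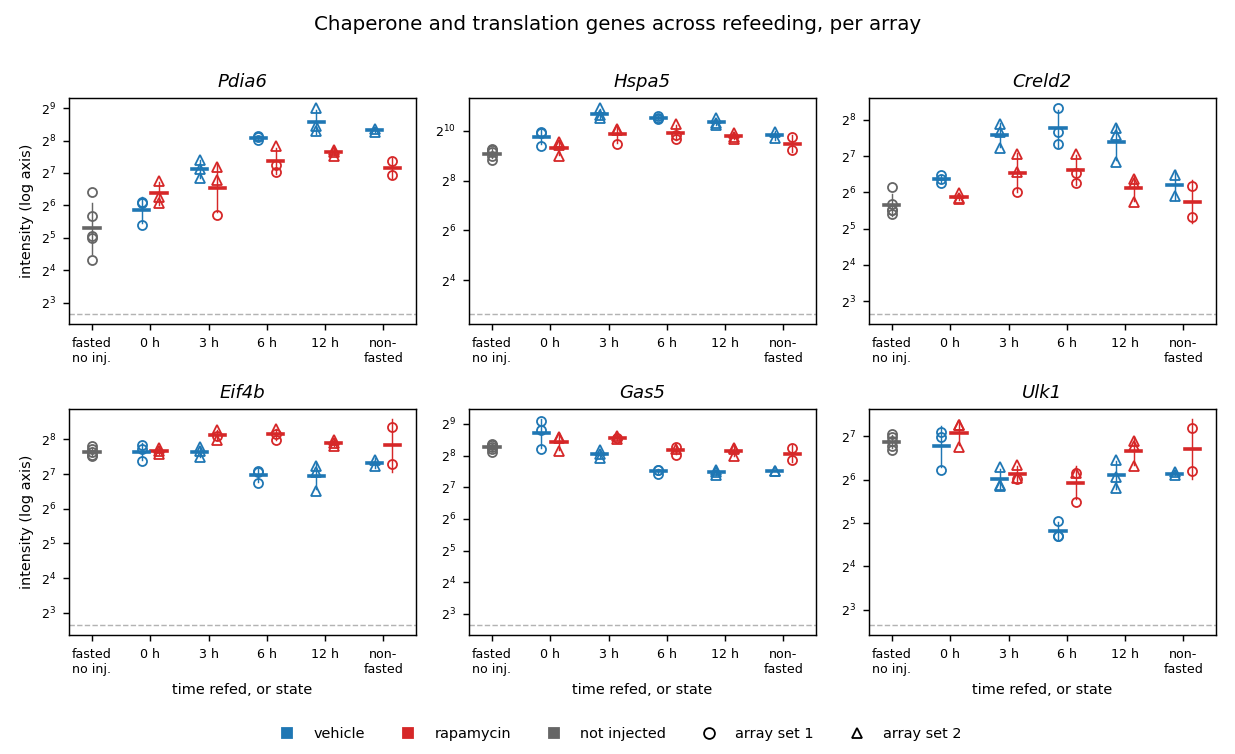
Intensity per array (vertical axis, log scale in base 2, floor of 6.31 dashed) by time refed or feeding state (horizontal axis) for 3 chaperone genes and 3 genes that were higher with rapamycin; bars are means of the log2 values and thin lines their SD, colour gives the injection and the symbol the array set. Eif4b averages 285 with rapamycin and 125 with vehicle at 6 h, and 237 and 125 at 12 h.

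In nonfasted mice (n = 2 each) the comparison asks what the drug changes without a fast, 24 h after the injection. Psapl1, a saposin-like gene, was higher with rapamycin at 64.0 ± 19.8 against 4 ± 4.24 (log2 change 3.23 ± 0.49), Ms4a1 at 1.31 and Nrbp1 at 1.13. Pctp, a phosphatidylcholine transfer protein, was lower at -2.92, and Avpi1, Jpt1 and Myo5b lay at the floor on both rapamycin arrays (at least 1.55-fold, at least 1.27-fold and at least 1.23-fold lower). The heat shock gene Dnajb1 was lower at -2.43, Tsc1, a brake on mTORC1, at -1.95, Dbt at -1.36 and Cyp4a14 at -0.52. Fasn stood at 0.88, Srebf1 at 0.62, Pck1 at -1.25 and Igfbp1 at -1.98, none passing (adjusted p from 0.125 to 0.859).

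In all 5 probe sets were higher and 61 lower, but the vehicle arrays belong to set 2 and the rapamycin arrays to set 1, and with the array set as a term 4 were higher and 2 lower (3 called in both). Of the genes named here Ms4a1 alone passed with the term (log2 change 1.63, adjusted p = 0.0159). The split was 25 to 55 after quantile normalization and 15 to 46 after scaling to 1 trimmed mean. There were 30, 34 and 31 calls without vehicle replicate 1 or 2 or rapamycin replicate 1, with the lone array assumed to vary like the other groups.

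Whether rapamycin changed the refeeding response itself was tested as an interaction over 3, 6 and 12 h against 0 h. The response of cholesterol synthesis genes at 3 h was smaller with the drug in 10 of 16, with 13 adjusted over the list alone (camera adjusted p = 1.88e-10; adjusted p = 0.226 with an estimated correlation; no gene with the array set as a term). At 0 and 3 h the effect of the drug on Idi1 was 1.22 and -2.73 without the term and 2.13 and -3.04 with it. For Cyp51 it was 0.72 and -3.73 without the term and 1.06 and -3.84 with it, and for Msmo1 -0.14 and -3.60 without and -0.45 and -3.50 with it. Over all probe sets 86 passed the F-test, and 6 did with the term, against 15 with the term and a floor of 30. By time, the log2 difference between the drug effect and that at 0 h was above 0 for 18 probe sets and below 0 for 294 at 3 h, for 0 and 1 at 6 h, and for 4 and 22 at 12 h. This sign is not the size of a response, as some genes fall on refeeding. With the term the counts were 1 and 1, 2 and 2, and 2 and 2, so the count at 3 h depends on the array set. The F-test gave 30, 50 or 232 calls without vehicle 0 h replicate 1, 2 or 3, 45 or 53 without rapamycin 0 h replicate 2 or 3, 32 or 38 without vehicle 3 h replicate 2 or 3, 147 without rapamycin 3 h replicate 2 and 154 without rapamycin 6 h replicate 3.

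The size of the response with rapamycin relative to vehicle was the median ratio over probe sets whose response averaged over both drugs passed. It was 0.532 at 3 h (1007 probe sets; 0.394 to 0.639 on leaving out 1 array), 0.929 at 6 h (2269 probe sets; 0.790 to 1.02) and 0.825 at 12 h (2874 probe sets; 0.707 to 0.901). With the array set as a term it was 0.620, 0.861 and 0.816. The 3 rapamycin arrays taken singly gave 0.471 to 0.607 at 3 h, 0.847 to 0.963 at 6 h and 0.788 to 0.872 at 12 h. Over the 3 times the cholesterol synthesis genes had ratios of 0.00434, 0.796 and 0.731, and the gluconeogenic list had 0.764 at 3 h.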

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

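The tests of the array sets, of 1 array and of a common factor for cholesterol synthesis genes were chosen only after the result was seen. The test of a common factor for chaperone genes and the splits of the samples were not. The reading of that chaperone test with the array set as a term was added to the rule fixed beforehand.

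The number of probe sets higher with rapamycin at 0 h, 314 against 38 lower, is a pattern open to a technical source. Inside the rapamycin groups at 3 and 6 h, where arrays of both sets occur, 92.02% of the probe sets called at 0 h differed between the sets in the same direction, against 64.2% of all tested probe sets. With the array set as a term 3 probe sets passed, 2 of them among the 352 called before, and the median change of the higher calls went from 1.64 to 0.64 while their median SE went from 0.385 to 0.466. A difference between the array sets may account for most of these calls. An effect of rapamycin given 2 h before cannot be told apart from it, because all vehicle arrays at 0 h belong to set 1 and all rapamycin arrays to set 2.

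Cholesterol synthesis genes, lower with rapamycin at 3 h, were set against 3 other explanations: the array sets, a common factor for the response, and 1 array. With arrays of set 2 alone the median over the list was -1.46 and 15 of 16 genes were below 0, which argues against the array sets. A common factor for the whole response at 3 h would give this list the ratio of 0.532 found over all responding probe sets (SD 0.0685 over the 3 rapamycin arrays at 3 h alone), but its ratio was 0.00434, and -0.0134, 0.148 and -0.0970 on the single rapamycin arrays. Leaving out 1 array moved the 0.532 between 0.394 and 0.639. The list was singled out for its fall at 3 h on these same arrays, and that fall enters its ratio. A low ratio was therefore partly built in and is not independent support. The 0 h arrays differ in array set between the drugs, and with the array set as a term the ratios were -0.0104 for the list and 0.620 over all responding probe sets. Without any 1 of the 6 arrays the median stayed between -2.08 and -1.26, which argues against 1 array. A candidate explanation is that rapamycin delays the rise of this pathway, as the ratio was 0.796 at 6 h and 0.731 at 12 h. This was seen in the same data and was not tested. The ratio did not rise further from 6 to 12 h, and that over all responding probe sets also was higher than at 3 h (0.929 and 0.825).

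Chaperones of the endoplasmic reticulum were lower with rapamycin over 3, 6 and 12 h, and their median was -0.21 both at 0 h and in nonfasted mice. With each time compared inside 1 array set the median was -0.435 and 21 of 22 genes were below 0, which argues against the array sets. A common factor for the whole response stays open. The averaged ratio of the list was 0.465 (SD 0.0705) against 0.762 (SD 0.0345) over all responding probe sets, but 0.720 against 0.765 with the array set as a term. By the rule fixed beforehand, which used the first pair alone, a common factor would not account for the list. The comparison with the array set as a term was not part of that rule. The first pair rests on 0 h arrays that differ in array set between the drugs, so with the second pair beside it the test could not decide.

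In the uninjected fasted mice 4 of 32 quantities had 1 array far from the other 4, where chance gives about 1 in 20. For genes the gap was taken on the floored log2 values, while the values in brackets are intensities. The gap to the nearest array over the whole range was 0.865 for Nnmt (replicate 5 at -25 against a mean of 118), 0.730 for Pak4 (replicate 4 at 158 against 69.6), 0.844 for Csf1r (replicate 2 at 259 against 125) and 0.714 for Pck1 (replicate 5 at 1966 against 2399). The far array of Nnmt lay under the floor, so its gap depends on the floor.

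The effect of rapamycin differed between 0, 3, 6 and 12 h for 86 probe sets by the limma F-test, and for 18 of 125 named genes. Adjusted p was 0.0144 for Cyp51, 0.0244 for Msmo1, 0.0301 for Idi1, 0.0288 for Sqle and 0.0288 for Mvd among cholesterol synthesis genes. It was 0.0108 for Bhlhe40 and 0.0166 for Nr1d2 among clock genes, 0.0257 for Pik3r1, 0.0288 for Hba-a1, 0.00928 for Pml, 0.00758 for Umps, 0.00937 for Pnliprp2, 0.038 for Tmem62, 0.0302 for Jpt1 and 0.0458 for Rrm2. It was 2.66e-04 for Pak4, 0.00361 for Pag1 and 9.68e-06 for Foxk2, the 3 of these 18 that passed with the array set as a term too. All 12 h arrays were at or under 30 for Pag1 and Foxk2, so their p-values rest on values near the floor and show no change above background. Pak4 lay at the floor on all 3 vehicle arrays at 0 h but averaged 87.3 in uninjected fasted mice, so its p-value rests on the vehicle 0 h group. Pml and Umps averaged 0.667 and 4 in vehicle mice at 0 h but 58.2 and 39.2 in uninjected fasted mice. Their p-values therefore rest largely on the vehicle 0 h group too. Each gene stands for 1 probe set here. A further probe set of Mid1ip1 passed (0.00361; 0.0121 with the term), as did one of Fdps (0.0229; 0.153 with the term).

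Other splits of the same arrays gave fewer calls than the real one in most comparisons. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 352 and 336 for rapamycin at 0 h, 20 and 2 at 3 h, 1 and 3 at 6 h, and 21 and 8 at 12 h. They were 1471 and 189, 1384 and 81, and 2316 and 45 for refeeding at 3, 6 and 12 h. For rapamycin at 6 h 5 of 10 splits gave as many calls, and in the other comparisons 1 did, the real one. For the injection 1 of 56 splits gave as many, the real one (386), but the highest other gave 381, nearly the same. For the interaction 4 of 100 did (real count 86, highest other 202). Both shares are under the threshold. Since other splits gave nearly as many calls or more, the shares alone do not exclude chance. For the interaction 3 other splits gave more than the real count, which points to structure among the samples, and with the array set as a term the count was 6. The splits that gave 336 and 381 calls keep vehicle 0 h replicates 1 and 2 together against replicate 3, and for the injection the splits with 224, 187, 158 and 155 calls do so as well, which points to a structure among these 3 samples.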

How the results depend on the processing

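The array set as a term, the floor of 30, both together, the scaling to 1 trimmed mean and the mean effect of rapamycin were chosen only after the data were seen. The values followed were 244, each for 1 gene in 1 comparison. Of these 239 kept direction and side of the threshold with a trended robust prior, 234 and 233 with the floor halved or doubled, 233 with no detection filter, 231 scaled to 1 trimmed mean, 228 with quantile normalization, 214 with a replicate block, 202 with the floor of 30, 187 with the array set as a term, 176 with both and 145 with only the groups compared. Among probe sets present on 11 arrays 211 of 213 did so. Leaving out 1 array kept 1198 of 1465 values, with 230 weaker, 8 stronger and 29 moved. The cause was not tested unless stated.

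Quantile normalization gave 908 calls for refeeding at 3 h, 17 for the interaction and response ratios of 0.694 at 3 h and 0.890 at 12 h. The halved floor gave 3 calls for rapamycin at 6 h, and the doubled floor 33, 3 and 36 at 3, 6 and 12 h and 55 for the interaction. Nonfasted rapamycin had 107 calls with no filter and 34 present on 11 arrays, and rapamycin at 0 h 228 with the latter. A replicate block gave 0 calls at 6 h, 10 at 12 h, 129 for the injection and 39 for the interaction. With only the groups compared, which leaves fewer arrays for the spread, limma gave 142, 1, 0 and 0 calls for rapamycin at 0, 3, 6 and 12 h and 0 in nonfasted mice. It gave 579, 443 and 1261 for refeeding at 3, 6 and 12 h, 18 for the injection and 794 for nonfasted mice.

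The array set as a term gave 3 and 4 calls for rapamycin at 0 and 6 h, 6 in nonfasted mice, 176 and 1023 for refeeding at 3 and 12 h, 1034 for nonfasted against fasted mice, 6 for the interaction, and ratios of 0.620 at 3 h and 0.861 at 6 h. The floor of 30 gave 100, 45, 6 and 68 calls for rapamycin at 0, 3, 6 and 12 h and 44 for the interaction. Both together gave 0, 34, 7 and 77 calls at these times, 20 in nonfasted mice, 194 and 981 for refeeding at 3 and 12 h, 979 for nonfasted against fasted mice, 15 for the interaction and a ratio of 0.637 at 3 h. Scaling to 1 trimmed mean gave 2 calls at 6 h. Reversed were Mki67 at 0 h with the array set as a term (-0.34) and, with both, Cttn (0.0449), Pik3r1 (-0.13), Bhlhe40 (-0.17) and Nr1d2 (-0.21) at 0 h and Etv4 in nonfasted mice (0.10). Of 310 list tests 89 passed with the preset correlation, 9 with an estimated one, 8 with that and the array set as a term, 84 by fry.

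Leaving out 1 array gave 164 to 866, 6 to 51, 0 to 7 and 5 to 34 calls for rapamycin at 0, 3, 6 and 12 h, 30 to 67 in nonfasted mice, 918 to 1920, 1027 to 1489 and 1914 to 2300 for refeeding, 59 to 1141 for the injection, 1117 to 1967 for nonfasted against fasted mice, and 30 to 232 for the interaction. The ratios ran from 0.394 to 0.639, 0.790 to 1.02 and 0.707 to 0.901 at 3, 6 and 12 h. At 6 h 392 probe sets had an unadjusted p under 0.05, at 12 h 524 and in nonfasted mice 835. The other deposited table was not run, as its values are the same for all 12488 probe sets. Values near the floor limit what can be seen, since 24.2% to 40.8% of values lay at or below 0.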

Other observations

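The mean effect of rapamycin over 3, 6 and 12 h, its tests and its alternatives were chosen only after the data were seen, except the splits of the samples. The genes named here were chosen after their values were seen. Over 9 rapamycin and 9 vehicle mice, chaperones of the endoplasmic reticulum were lower in 8 of 22 genes and higher in none. Hspa5, the main chaperone of that compartment, averaged 933 with rapamycin and 1476 with vehicle (log2 change -0.67 ± 0.11, SE), Creld2 stood at -1.16, Manf, a secreted stress protein, at -1.06, Dnajb11 at -0.70 and Hsp90b1 at -0.46. The 8 genes also include Ssr3 at -0.54 and Sec61a1 at -0.50, which act in protein entry into that compartment, and outside the list Ostc, a subunit of the glycosylating enzyme there, was lower at -0.80. The chaperone list passed (camera adjusted p = 1.70e-17; adjusted p = 0.0304 with an estimated correlation; 16 lower adjusted over the list alone).

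Of translation factors 3 of 26 were higher, Eif4b at 0.87 ± 0.11 (adjusted p = 2.54e-04), Eif4a2 at 0.37 and Pabpc1, a poly(A)-binding protein, at 0.25, while the list as a whole did not pass (camera adjusted p = 0.374). Gas5, a noncoding host gene of small nucleolar RNAs, was higher at 0.61, Cox7a2l at 0.54 and Ulk1 at 0.60. Ribosome biogenesis genes were lower in 5 of 38, among them Nop56 at -0.997 and Gnl3 at -1.40, and the list lost its call with an estimated correlation (camera adjusted p = 1.29e-05; adjusted p = 0.0908 with an estimated correlation; 13 lower adjusted over the list alone). Gnl3 averaged 8.89 with rapamycin and 25.8 with vehicle, both under 30, so its log2 change is not exact. Nop56 averaged 18.1 and 36.0. Cholesterol synthesis genes were lower in 5 of 16, with Cyp51 at -1.48, Msmo1 at -1.31 and Lss at -1.19 (camera adjusted p = 4.91e-13; adjusted p = 0.0728 with an estimated correlation; 12 lower adjusted over the list alone). The means of Cyp51 and Msmo1 rest on 3 h, as Cyp51 stood at -3.73, -0.19 and -0.52 and Msmo1 at -3.60, -0.04 and -0.30 at 3, 6 and 12 h.

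In all 27 probe sets were higher and 69 lower in this mean effect, and 32 and 83 with the array set as a term (96 called in both). The share of set 2 arrays differs between the drugs in opposite directions at 3 and 6 h, and not at 12 h. The term therefore left the log2 changes as they were and altered only their standard errors, so it does not test the array sets here. After quantile normalization 60 were higher and 73 lower, and the total was 145 with the floor doubled, 170 with the floor of 30 and 181 with that floor and the array set as a term. There were 61 to 125 calls on leaving out 1 array. They were 63 and 61 without vehicle 3 h replicate 2 or 3, and 63 each without vehicle 12 h replicate 2 and rapamycin 12 h replicate 3. Of 100 splits within the times 1 gave as many calls, the real one with 96 against 3 for the highest other. A random split of these arrays is thus unlikely to give this count. The mean effect was itself chosen after the data were seen, which the splits do not cover.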
